A study of Arabidopsis thaliana with 12 samples.

How the data were processed

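The series holds 12 arrays of 2 colours on which amplified RNA from membrane-bound and free polysomes of 2-week-old Arabidopsis seedlings was hybridised, from 3 fractionations with 4 arrays each. Per the labels, MBP was in Cy3 and FP in Cy5 on 2 arrays of each fractionation, and the dyes were swapped on the other 2. The authors deposited 1 log ratio per probe row and array, taken here as log2. The scale, the centring method and the direction of the ratio are not given in the sources used here; base 2 is the convention for such arrays, and with a natural log the sizes in log2 units would be larger. Background correction, normalization and array scanning are likewise not given. Array medians lay close to 0, so the authors' values were already centred in some way. In slide order 1 to 4 the medians were 0.02, 0.02, 0.00 and 0.01 for fractionation 1, 0.02, 0.03, -0.00186 and -0.00578 for fractionation 2, and 0.02, 0.01, 0.01 and 0.01 for fractionation 3.

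The log2 values were used as deposited, without recentring. Within a fractionation, the 2 arrays of each dye orientation were averaged and then the 2 orientations, so that a dye effect cancelled and the 4 technical arrays counted as 1 replicate. Both orientations and all 3 fractionations were required, which left out 1 feature. Rows annotated to 1 gene were averaged per gene and other rows entered under their own ID, which gave 12666 annotated and 10951 other features. The intercept was tested against 0 with limma 3.58.1 (lmFit and eBayes, 2 residual and 6.89 prior degrees of freedom) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The dye effect was tested in the same way on the difference between orientations (MBP in Cy5 minus MBP in Cy3). Lists of at least 3 features were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry.

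Of the rows annotated to 1 gene, 13785 were matched to a current locus by gene number and 57 kept the older symbol. Of 44 lists, 25 were written before the data were examined and 19 from symbol patterns after the annotation was seen. Of the 25, 12 had fewer than 3 annotated features and were not tested. These 12 were aquaporins, cellulose synthases and Golgi glycosyltransferases, lipid and sterol enzymes of the endoplasmic reticulum, soluble nuclear regulators, and transcripts of the chloroplast and mitochondrial genomes (0 features each), proteasome subunits and peroxisomal proteins (1 each), and ion pumps, chaperones of the endoplasmic reticulum lumen, translocon subunits and tail-anchored proteins (2 each). Of these features, 1 passed the threshold, a positive one among the lumen chaperones. The fry test, which asks whether the members of a list move 1 way and does not compare them with other features, passed 8 lists (lowest adjusted p = 0.00440) and was not used for calls.

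The rule fixed before the data were examined was to name the 10 annotated genes with the highest and the 10 with the lowest ratio that passed the threshold with 1 sign in all fractionations, the 2 largest members of each list with 1 opposing member, and the member of smallest p where a list had none past it. Because probes annotated to 1 gene did not share a ratio, that rule was reduced to the first 2 features on each side, printed by row ID. A planned comparison by hydrophobic segments of the encoded proteins was not run, because protein sequences were not used here. Identical values on all 12 arrays occurred in 478 sets of rows (969 rows), which were kept as separate rows and counted once in an alternative chosen after seeing the data.

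The tests were checked on simulated data with 3 values per feature for 23617 features at the median spread of the real ratios. Of 50 features each, 6% were recovered at a log2 difference of 0.25, 94% at 0.5 and 100% at 1 and at 2, with 6 false among 156 calls. The values were drawn as independent normal values with few changed features, whereas 28.2% of the real features passed the threshold. The adjustment therefore asked for a smaller unadjusted p in the simulation, and these shares do not give the power of the real test. The share of false calls likewise holds only for values drawn that way. Lists were also drawn from the real features. With 50% of their members above a ratio of 1, camera gave an unadjusted p under 0.05 in 88% of 100 lists of 9 features and in 100% of lists of 15, and with random members in 2% and 1%. At 0.05 divided by the 32 lists, a level close to what the adjustment asks of a single list, the shares with 50% of members above 1 were 7% for lists of 3, 11% for 6, 14% for 9, 89% for 15 and 100% for 27. No lists with negative or smaller shifts were drawn. Alternatives covered array centring and scale, each dye orientation alone, the median of arrays, missing values, single probes, variance moderation, a minimum fold of 1.5, all 12 arrays with the fractionation as a block, and leaving out each fractionation.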

Results

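The series compared messenger RNA on membrane-bound polysomes (MBP) with messenger RNA on free polysomes (FP) in Arabidopsis thaliana. Polysomes are messenger RNAs carrying several ribosomes; the membrane-bound kind sediments with membranes such as the endoplasmic reticulum, and the free kind stays in the cytosol. The plants were the aboveground parts of 2-week-old seedlings from 1 batch. Both polysome classes were isolated in 3 fractionations, and each pair of RNAs was amplified, labelled and hybridised to 4 arrays carrying 2 dyes. MBP was in Cy3 on 6 arrays and in Cy5 on the other 6. The fractionation was the replicate (n = 3), and because all plants came from 1 batch, p-values measured the spread of fractionation, amplification and hybridisation only. The value table held 24794 probe rows with 42 missing values, and no intensities were used here, so signal over background was unknown. With 3 fractionations, the tests had only 2 residual degrees of freedom.

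The first question was how many transcripts departed from the array centre in their ratio between the polysome classes. Array medians lay close to 0, so a ratio of 0 marks a typical row and need not mean equal amounts in both classes. Of 23617 features tested, 4048 had a positive and 2622 a negative log2 ratio past the threshold (limma, adjusted p under 0.05), which is 17.1% and 11.1% of the features. The positive side was much the longer. Of its 4048 features, 1562 lay above a log2 ratio of 1 and 255 above 2, whereas 5 of the 2622 negative features lay below -1. The median log2 ratio was 0.77 among the positive features, a 1.71-fold difference, and -0.40 among the negative features, a 1.32-fold difference. The sign was the same in all 3 fractionations for 4045 of the positive and 2621 of the negative features, which the test on those same 3 values largely requires. Both dye orientations had the sign of the mean for 3969 of the 4048 positive and 2453 of the 2622 negative features. The remaining 16947 features did not pass the test, and the smallest absolute ratio that passed was 0.26. The negative count was the less stable: it was 1419 without fractionation 3. It was 1731 with only the arrays that had MBP in Cy3 and 3149 with only those that had MBP in Cy5. Against a minimum fold of 1.5, 1680 positive and 15 negative features passed.

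The deposited values do not state which polysome class is the numerator. Array titles name MBP before FP, and MBP is channel 1 on every array. All 36 pairs of arrays with opposite dyes correlated positively across probe rows (r from 0.470 to 0.610), so the values already run 1 way. A positive ratio is therefore likely higher in MBP, relative to the array centre, on the basis of that order of names alone. The list of secreted cell wall proteins, chosen to anchor the direction, had a mean of 0.18 and a median of -0.06 over 9 annotated genes (camera p = 0.683) and did not settle it. Counts and sizes are given below for the positive and the negative side.

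**Figure D1:**
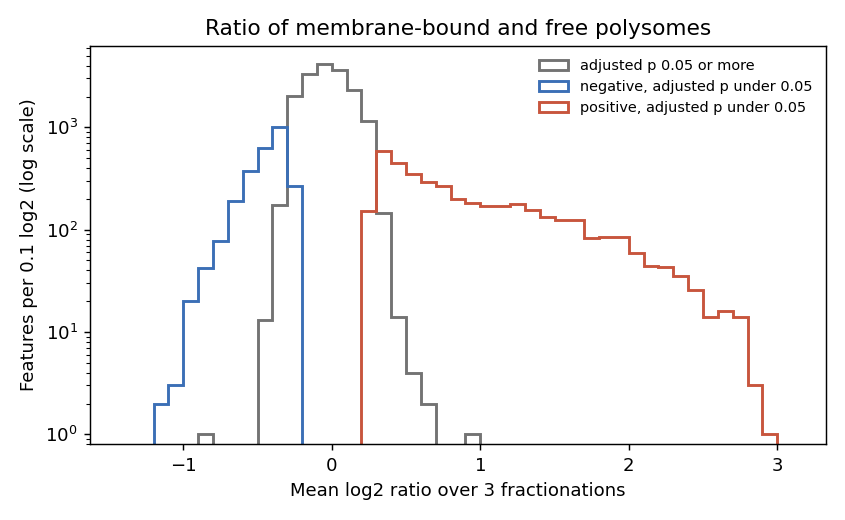
Number of features per 0.1 of mean log2 ratio over 3 fractionations, on a log count axis, with separate outlines for features not past the threshold and for positive and negative features past it (limma, adjusted p under 0.05). The positive outline extends to 3.00 and the negative outline to -1.19.

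Over all features the median log2 ratio was -0.01, the middle 50% lay between -0.16 and 0.17, and the upper 1% began at 2.02. Among annotated features past the threshold with the same sign in each fractionation, row ID 9824 had the highest ratio, 3.00 ± 0.03 (SD, n = 3), a 7.99-fold difference with limma adjusted p = 3.63e-07. Row ID 8805 followed at 2.77 ± 0.10 (SD, n = 3), although its ratio also differed between dye orientations, by -0.99 with MBP in Cy5 against MBP in Cy3 (limma adjusted p = 0.0232). On the negative side, row ID 13228 stood at -1.04 ± 0.17 (SD, n = 3; limma adjusted p = 3.90e-05) and row ID 6546 at -1.0 ± 0.09 (SD, n = 3; limma adjusted p = 2.58e-05), the latter with a dye difference of -0.67 (limma adjusted p = 0.0474). The order holds among annotated features, in which rows annotated to 1 gene were averaged. Over all features, 5 negative ones past the threshold lay below -1 and the lowest ratio was -1.19. The 2 negative rows are therefore not the extremes of that side. Taken singly, 1 more annotated row, averaged here with another, passed the threshold and lay lower than both negative rows, at -1.26, and no such row lay above the 2 positive ones. These rows are given by ID because probes annotated to 1 gene did not share a ratio, as described below.

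The second question was how far the isolation repeated. Across features, the log2 ratios of fractionations 1 and 2 correlated with r = 0.841 and rho = 0.621, those of 1 and 3 with r = 0.855 and rho = 0.627, and those of 2 and 3 with r = 0.872 and rho = 0.675. Features are not independent replicates, so no p is given. The median SD over the 3 fractionations was 0.15. Single arrays of the same dye orientation correlated with a mean r of 0.724 within a fractionation and 0.685 between fractionations, and arrays of opposite orientation with 0.561 and 0.535. Orientation thus separated the arrays more than fractionation did.

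**Figure D2:**
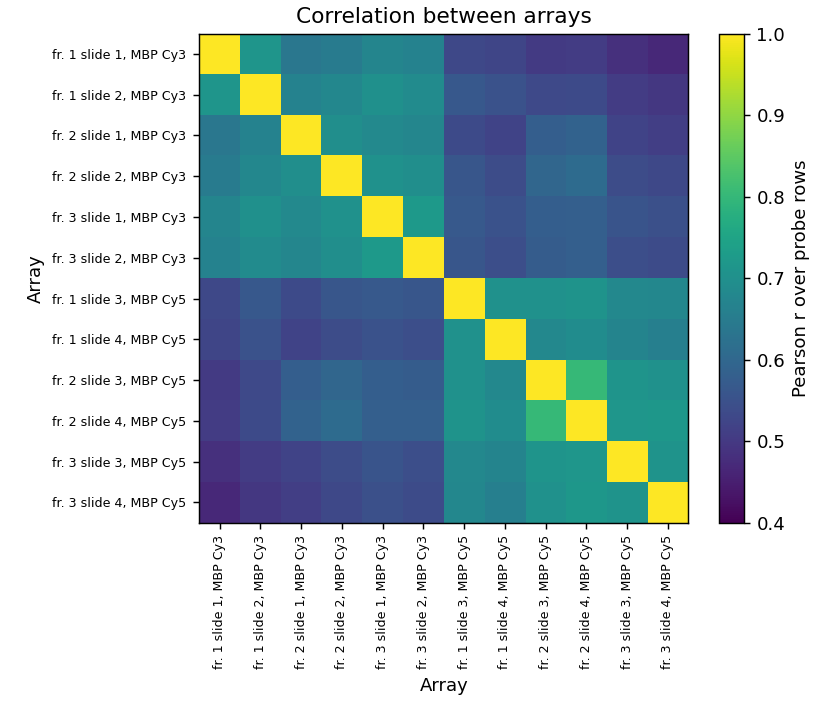
Pearson r over probe rows for each pair of the 12 arrays, ordered by the dye of MBP and then by fractionation (fr.). The 2 blocks of 6 arrays with the same orientation are brighter than the blocks between orientations, where r lies between 0.470 and 0.610.

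The dye swap gave the dye effect within each fractionation. The ratio was higher with MBP in Cy5 for 830 features and higher with MBP in Cy3 for 1427, together 9.56% of 23617 (limma, adjusted p under 0.05, n = 3). The largest differences were 1.90 and -2.27 on the log2 scale, and the median absolute difference was 0.24. Of the features with a dye effect, 852 also passed the test of the ratio itself, and in 526 of these the dye difference exceeded the ratio in size. The ratio averages both orientations, so each departed from it by less than the full difference between them. Leaving out any of the fractionations gave 0 features past the threshold with limma. At an unadjusted p under 0.05 there were then 5467 to 5530 features, against 7066 with all 3. Any other difference between the 2 sets of slides goes with the orientation and cannot be told apart from dye.

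Gene names came from an annotation of the row IDs, which gave 1 gene for 13842 rows, several for 1 row and none for 10951. Its names were checked on genes with more than 1 probe. In 1252 pairs of probes annotated to 1 gene, the mean log2 ratios of the 2 probes correlated with r = -0.00401 (rho = 0.0194), although those same probes repeated between fractionations with a mean r of 0.863. When gene labels were shuffled over these probes 1000 times, 95% of the correlations lay between -0.0554 and 0.0542. Both probes lay above 1 in 4 pairs, against 6.37 for unrelated probes, and only 1 of the probes did in 171 pairs. In 50 pairs the probes passed the test with opposite signs, and in 37 both passed it as positive. The numbers that unrelated probes would give were not computed for these 2 counts. At the level of row order, values and annotation did go together. Of 170 neighbouring pairs of annotated rows with identical values on all 12 arrays, 0 had the same gene, where 15.3 would be met by chance. Of 478 sets of identical rows, 164 were annotated to different genes and 0 to 1 gene. The other sets fell in neither class and carry no weight here. The ratios themselves did not bear out the names, so no row is called by a gene name here, and the gene groups below are groups of annotated rows.

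**Figure D3:**
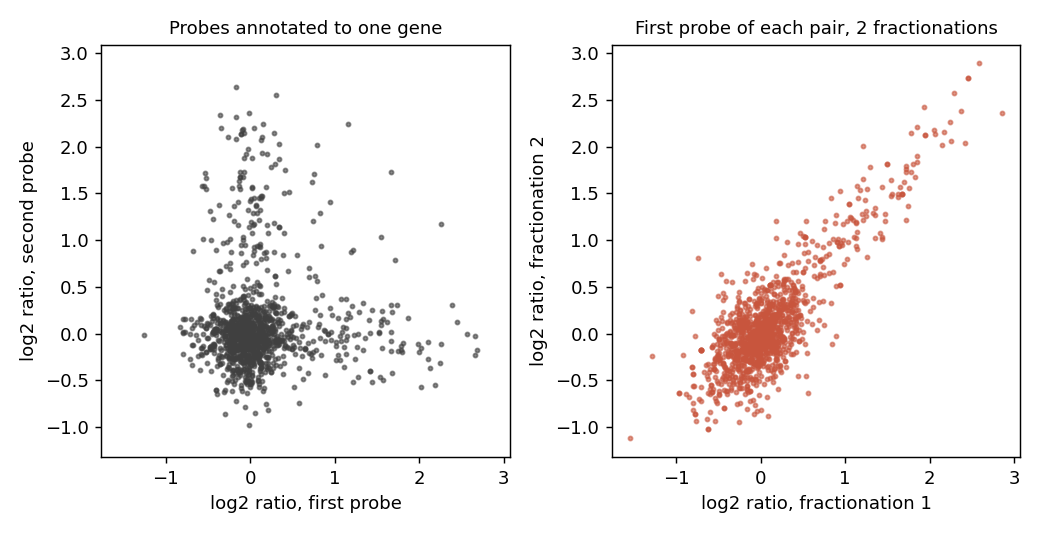
Left, mean log2 ratio of the first and second probe of each of 1252 pairs annotated to 1 gene (r = -0.00401). Right, the first probe of each pair in fractionation 1 against fractionation 2 (r = 0.838), with each point a probe.

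The third question was whether groups of proteins made on membranes or in the cytosol stood apart. None of 32 lists with at least 3 annotated features passed limma's camera test (lowest adjusted p = 0.707), and none passed with an estimated correlation (lowest adjusted p = 0.919). Most planned lists were too small for this to show that they did not stand apart: 12 of the 13 tested had 9 or fewer members. At an unadjusted p of 0.05 divided by the 32 lists, camera called 7% to 14% of lists of 3 to 9 features drawn with 50% of members above a ratio of 1. Lists with negative or smaller ratios were not drawn, so the power for those is unknown, for larger lists as well. Of the 32 lists tested, 1 had an unadjusted camera p under 0.05, where 1.6 would be met by chance. Of the 461 features in these lists, counted once per list, 77 were positive and 46 negative past the threshold, together 26.7%, against 28.2% of all features tested. With the names not borne out by the ratios, these values describe the annotated rows and say nothing about where the named groups are translated.

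The counts below cover only list members with an annotated row. Among the tested planned lists these ranged from 8 of 225 cytochrome P450 genes to 15 of 28 histones, so they do not stand for whole families. Among lists of membrane, secretory and endomembrane proteins fixed before the data were examined, the 9 secreted cell wall rows, of 42 genes listed, had 1 positive and 1 negative member past the threshold. The 4 receptor kinases and hormone receptors and the 3 membrane-tethered transcription factors had none (medians -0.01 and 0.16). Vacuolar and apoplastic hydrolases and defence proteins had 0 positive and 1 negative of 6 (median 0.05), and cytochrome P450 monooxygenases, enzymes anchored in the endoplasmic reticulum, had 1 and 1 of 8 (median -0.09). Among lists of soluble or organelle proteins, cytosolic ribosomal proteins had 1 positive and 2 negative of 9 (median -0.10), histones 0 and 2 of 15 (median -0.02), and tubulins and actins 2 and 1 of 9 (median -0.05, mean 0.39). Cytosolic glycolysis and chaperones had 0 and 2 of 3 (median -0.39), and Calvin cycle enzymes, which fix carbon in the chloroplast, 1 and 1 of 3 (median 0.07). Photosystem and electron transport proteins had none of 9 (median 0.06, mean -0.01), nuclear-encoded mitochondrial proteins 0 and 1 of 4 (median -0.04), and WRKY transcription factors 2 and 0 of 9 (median 0.16). Adjusted over the list alone, the counts were the same as over all features for 12 of these 13 lists; the exception was cytosolic glycolysis and chaperones, with 1 positive and 2 negative.

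Lists drawn from gene symbols once the annotation was known, but before ratios of genes were read, did not pass either. Their counts too cover only members with an annotated row, from 17 of 156 secreted peptides to 14 of 16 tetraspanins. Of secretory and membrane families, serine carboxypeptidase-like proteins had 2 positive and 1 negative of 27, beta-glucosidases and beta-galactosidases 4 and 1 of 15, TRICHOME BIREFRINGENCE-LIKE proteins of the Golgi 0 and 3 of 23, and tetraspanins 3 and 4 of 14. SWEET sugar transporters had 5 and 0 of 13 (median -0.06, mean 0.37), glutamate receptor-like channels 1 and 1 of 9, CHX cation exchangers 1 and 0 of 6, PRA1 proteins 5 and 0 of 15, and secreted signalling and defence peptides 2 and 2 of 17. Of cytosolic and nuclear families, UDP-glucosyltransferases had 5 and 4 of 37, AGAMOUS-like factors 6 and 6 of 30, ubiquitin conjugation and removal enzymes 4 and 0 of 33, AUX/IAA, bZIP, bHLH and NGATHA regulators 6 and 4 of 30, and subunits of RNA polymerase, Mediator, LSM, RRP and THO complexes 8 and 1 of 30. IQ-domain proteins had 5 and 1 of 18, TON1 recruiting motif proteins 2 and 2 of 15, organelle PPR editing factors 2 and 3 of 13, and glutathione transferases 0 and 0 of 7. VPS and exocyst trafficking subunits had the lowest camera p (0.0221, adjusted 0.707, and adjusted p = 0.919 with an estimated correlation), with 8 positive and 1 negative of 18 and a median of 0.08. The mean was positive and the median negative for tetraspanins, secreted peptides, AGAMOUS-like factors, ubiquitin enzymes, IQ-domain proteins, organelle PPR factors and glutathione transferases, as for the SWEET, tubulin and cell wall lists. The direction given by camera was down for glutamate receptor-like channels and TON1 recruiting motif proteins, whose mean and median were positive. Adjusted over the list alone, 16 of these 19 lists kept their counts, while serine carboxypeptidase-like proteins had 0 positive and 0 negative, tetraspanins 4 and 5, and SWEET transporters 5 and 1.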

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

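The counts of positive and negative features stayed within 1.5 times 4048 and 2622 under most alternatives. Against a minimum fold of 1.5 (treat), which asks for a larger difference by its construction, 1680 positive and 15 negative features passed. With only the arrays that had MBP in Cy3, 1731 negative features passed, and with only those that had MBP in Cy5, 3149. The negative count thus differed between the dye orientations, and the cause was not tested. Leaving out 1 fractionation gave 3279 to 3880 positive and 1419 to 2276 negative features, the lowest counts without fractionation 3, and fewer samples are part of that alternative. With all 12 arrays and the fractionation as a replicate block plus a dye term, 4681 positive and 3772 negative features passed, and without the dye term 4686 and 3669. The estimated correlation within a block was 0.094 and -0.0133, respectively. These 2 fits thus counted the technical arrays nearly as independent replicates, and their higher counts add no evidence. Testing each row on its own gave 4178 and 2769, and counting identical rows once, an alternative chosen after seeing the data, 3980 and 2563. The dye effect went from 2257 features to 0 without any 1 of the fractionations, where the lowest adjusted p ranged from 0.0892 to 0.107, while 23.2% to 23.4% of features had an unadjusted p under 0.05, against 29.9% with all 3. The mean correlation between fractionations, 0.856, was 0.790 with only MBP in Cy3 and 0.797 with only MBP in Cy5, alternatives that average 2 arrays in place of 4. The correlation between probes annotated to 1 gene, a result added after seeing the data, was 0.0114 with only MBP in Cy3 and 0.0194 as Spearman's rho, against -0.00401. These values are small beside the range of -0.0554 to 0.0542 from shuffled labels, which was computed for the first fit. No change is read from them. No list passed camera under any alternative run (lowest adjusted p = 0.221), and 55 of 512 list medians had the other sign from the first fit, none of them past the threshold. Some of the 512 could not change sign, because variance moderation and the estimated correlation alter only the test and keep the median. Of the 32 lists, 21 changed the sign of their median in at least 1 alternative. The 4 rows named by ID stayed past the threshold with their sign in each of the 16 alternative fits. The hydrophobic segments and their second threshold were not run, and using any measured array was not run for the dye effect, which needs both orientations. Signal over background was not used here, so its limits are unknown.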

Other observations

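The tests in this part on noise, ID shift, identical rows, shuffled labels and centring were chosen after the result was seen. Those on dye bias and on sign patterns were written down before their results.

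Probes annotated to 1 gene did not share a log2 ratio (r = -0.00401 in 1252 pairs). Random measurement noise is argued against by the mean r of 0.863 between fractionations for the same probes. Low signal in 1 probe of a pair was not tested, since no intensities were used here. A constant shift of the row IDs is argued against by the highest r of 0.120 over 2000 shifts of up to 1000 IDs either way. Values attached row by row to other IDs than the annotation's are argued against by the identical rows: 0 of 170 identical neighbouring pairs were annotated to 1 gene, while each of the 2000 shifted annotations gave at least 4. An exchange of values between probes before the rows were listed per gene would keep that row structure and stays open, since any cause of a correlation near 0 would put -0.00401 inside the range given by shuffled gene labels; probes of 1 gene that pick up different transcripts were not tested.

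The positive tail of the ratios was longer than the negative tail, with 1689 rows above 1 and 6 below -1. With each array centred on its median, these counts were 1672 and 10. Dye bias is argued against, since the number above 1 exceeded the number below -1 by at least 4.83 times in each orientation of each fractionation. Array centring is argued against as well: the distance from the median to the upper 1% was at least 2.70 times that to the lower 1% in each fractionation, and no shift of the values changes these distances. Other steps of the authors' normalization were not tested. The biological explanation that the design offers, a limited class of transcripts translated mainly on 1 kind of polysome, may account for the tail, but the row names could not be used to test it.

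For the counts themselves, the 3 fractionations allow only 4 patterns of sign, too few for a share under 0.05. The real pattern gave 6670 features past the threshold for the ratio and 2257 for the dye effect, and was the only 1 of the 4 to reach its count in each. The highest count among the other patterns was 0 in both (limma), with 72 to 114 features at an unadjusted p under 0.05 for the ratio and 290 to 301 for the dye effect. Turning 1 fractionation breaks the common sign of every feature that repeats. Low counts in the other patterns therefore follow from the repeatability already given and add nothing to it.

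Identical values on all 12 arrays joined rows with neighbouring IDs in 472 of 478 sets. Because of such rows, the 1252 pairs of probes annotated to 1 gene held 1218 distinct pairs of values, which correlated with r = -0.00350. In 164 sets the rows were annotated to different genes.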
